A study of Mus musculus with 8 samples.

How the data were processed

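Total RNA from the left ventricle of male C57BL/6 and MRL/MpJ mice, 2 to 4 months old, was measured on 8 Affymetrix mouse arrays, with 1 array for each strain and time point (untreated, and days 3, 30 and 60 after ligation of the left anterior descending coronary artery). The labels do not state whether an array holds RNA of 1 animal or of several. The deposited values are signal intensity on a linear scale, made with MAS5 per the submitters' processing notes, for 22626 probe sets per array. Each array had been scaled as a whole by the authors: the trimmed mean signal lay between 247.1 and 248.3 in every array, while the median signal ranged from 112.8 to 139.5. Affymetrix control probe sets were not analysed here, so ratios of 3 prime to 5 prime signal and hybridisation controls were not used. Detection calls were not used here either.

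Probe sets were joined to genes through the platform's own annotation table. A single gene symbol was given for 20380 probe sets, several symbols for 691 and none for 1555, and 0 symbols had to be updated through the gene identifier. Probe sets with exactly 1 symbol covered 12393 genes, and each gene was represented by the probe set with the highest mean log2 signal over the 8 arrays. An offset of 28.6, the 20th percentile of all values, was added before the log2 transformation, and no further normalization was applied. Genes at or above a signal of 121, the median of all values, in at least 2 of the 8 arrays were kept, whatever the groups of these arrays, which left 8208 genes. Folds printed here are ratios of values with the offset added unless a signal is given. Both the number of arrays and the background signal limit the precision: differences between signals near or below the offset are compressed.

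Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the 8208 genes and a call at an adjusted p under 0.05. With 1 array per group there was no replicate within a group. The additive model with strain and time point therefore took its error from the strain-by-time differences plus the spread between arrays, with 3 residual degrees of freedom. From it came the strain difference (4 arrays against 4, time point as block), each day against untreated (2 arrays against 2, strain as covariate), day 30 against day 3, and day 60 against day 30. Interaction terms, with 2 residual degrees of freedom, asked whether the strain difference in the ligated pairs departed from that in the untreated pair, and whether the difference in the day 3 pair departed from that in the other pairs. Within a strain, 1 array against 1 gave changes without a test, counted at a 2-fold limit. The p-values of these gene tests measure the spread between these arrays, not the spread between animals in general.

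Lists of genes for heart muscle, matrix, wound repair, immune cells, other cell types, metabolism and signalling were set up, 38 in all, and 33 were tested. Mast cell, epicardium and red blood cell lists were left out because they had 4, 3 and 4 measured genes, fewer than the minimum of 5, and the other lists left out served the checks of strain and sex. Lists were tested with limma's camera, once with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 33 lists of a comparison. Camera sets the genes of a list against the other genes. With the preset correlation its p-values therefore rest mainly on the spread between genes, not on that between arrays or animals. Members were also tested with adjustment over the list alone. For 1 array against 1, a list's median was set beside 10000 random lists matched on mean signal.

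The tests, gene lists, filter, offset, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, for each comparison, up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold and with the same direction in every pair of arrays; where none passed, it names the 5 with the smallest unadjusted p. It also names up to 4 members of a list with the largest change and any member needed to show that members moved apart, and the 10 largest and 10 smallest differences between the strains' changes on each day. Genes named outside the rule are marked as such.

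The procedure was tested on simulated data with the same design and 200 changed genes. For the strain difference, 53.7% of 2-fold, 97.0% of 4-fold and 100% of 8-fold changes were recovered, with 7 false calls among 174. For day 3 against untreated the shares were 10.4%, 82.1% and 97.0%, with 13 false calls among 139. Of 4 simulated lists shifted by a log2 of 0.5, camera called 4 with the preset correlation and 0 with an estimated one. It called 0 lists that had not been shifted. Genes were simulated independently of each other, so this does not show how the preset correlation does on lists whose genes vary together. With an estimated correlation camera missed all 4 shifted lists. A list that fails with it here is therefore not shown to be unchanged. Alternatives tried were quantile normalization, centring of arrays on their medians, an offset 4 times smaller or larger, no filter, a filter on the mean signal, all probe sets, an intensity trend in eBayes, a 3-fold limit, an estimated correlation, no time block, both day 3 arrays left out, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.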

Results

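Gene expression was measured in the left ventricle of C57BL/6 mice, a common inbred reference strain, and of MRL/MpJ mice, a strain known for closing ear wounds with little scarring. The left anterior descending coronary artery was tied off (LAD ligation), which infarcts the left ventricle, and hearts were taken after 3, 30 or 60 days; the hearts for comparison were untreated, not sham-operated. Each of the 8 combinations of strain and time point had 1 array, so no value has a replicate of its own group. Signals correlated across the 8208 genes kept (log2 values with the offset added, and genes are not independent replicates). For the 21 pairs of arrays without the C57BL/6 day 30 array r lay between 0.884 and 0.948. The 7 pairs with that array had r between 0.844 and 0.877, and its highest signal was 75193, against at most 38118 in the other arrays. H2-Ea, a class II gene that C57BL/6 mice do not transcribe, had signals between 5.6 and 105.6 over its 3 probe sets and all arrays. Nnt, a mitochondrial transhydrogenase gene that is defective in some C57BL/6 lines, had a signal of 3040 in untreated C57BL/6 and 5762 in untreated MRL/MpJ, but 4863 and 3962 on day 3. Neither gene separated the strains in every pair of arrays, so neither settles the strain on the labels. The Y-linked genes Eif2s3y, Kdm5d and Uty gave at most 172.9 in any array, too dim to check the sex on the labels. Xist, expressed from the inactive X chromosome of females, had signals of 85.8 to 336.3 on its strongest probe set and at most 126.6 on the other 2, so it does not settle the sex either.

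The strain difference asks which genes differ between the hearts of the strains whatever the time after injury. H2-K1 and H2-D1, 2 class I genes of the major histocompatibility complex whose products show peptides to T cells, had lower signals in MRL/MpJ on their main probe sets: H2-K1 by a log2 of -3.72 (SE 0.16, 4 arrays against 4) and H2-D1 by -2.70 (SE 0.16). H2-K1 signals were 4051 to 6395 in C57BL/6 and 255.6 to 502 in MRL/MpJ. Akr1e1, an aldo-keto reductase gene (log2 -2.73), Pttg1, which encodes securin (-2.63), and Rpgrip1, a gene for a ciliary protein (-2.60), were lower in MRL/MpJ too. Myl9, the regulatory myosin light chain of smooth muscle, was higher in MRL/MpJ by a log2 of 2.11 (SE 0.18), with 396 against 1375 in untreated hearts. In limma 18 of 8208 genes passed, 4 higher and 14 lower in MRL/MpJ, each in the same direction in 4 of 4 pairs, with adjusted p = 0.000177 for H2-K1, 0.000713 for H2-D1, Akr1e1 and Pttg1, 0.00556 for Rpgrip1 and 0.00566 for Myl9.

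The other genes higher in MRL/MpJ were Pam, an enzyme that amidates peptide hormones (log2 2.64), Hebp1, a heme-binding protein gene (2.24), and Nfia, a transcription factor (1.26). The other genes lower in MRL/MpJ were Parp3, a DNA repair gene (log2 -2.47), the kinase gene Stk25 (-2.29), Rps4l (-1.81), Sspn, which encodes sarcospan of the dystrophin complex (-1.75), and Ndufa12 of respiratory complex I (-1.48). Isca1, Gadd45gip1, Cyfip2 and Rab6b, with log2 -1.46, -1.43, -1.41 and -1.20, fell outside the naming rule and were chosen after their values were seen. Probe sets disagreed in sign for H2-D1, where 1 of 5 others was higher in MRL/MpJ (log2 2.56) and the other 4 lower (-3.07 to -0.48), and for Ndufa12, where 1 of 2 others gave 0.12. Others had the same sign but a smaller difference: 2 of 3 for H2-K1 (-1.11 and -0.83; the third gave -3.51), and the only other one for Isca1 (-0.098), Parp3 (-0.50) and Sspn (-0.76). The other probe set of Pttg1 gave a larger difference, -3.29. H2-K1, H2-D1, Akr1e1, Pttg1, Rpgrip1 and Myl9 passed in each of the 17 alternatives of the gene test. These are not all distinct for strain: leaving out either array of a time point removes that pair and gives the same fit. Without either untreated array 7 of the 18 genes remained, without either day 3 array 8, without either day 60 array 9, and without either day 30 array 11.

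**Figure D1:**
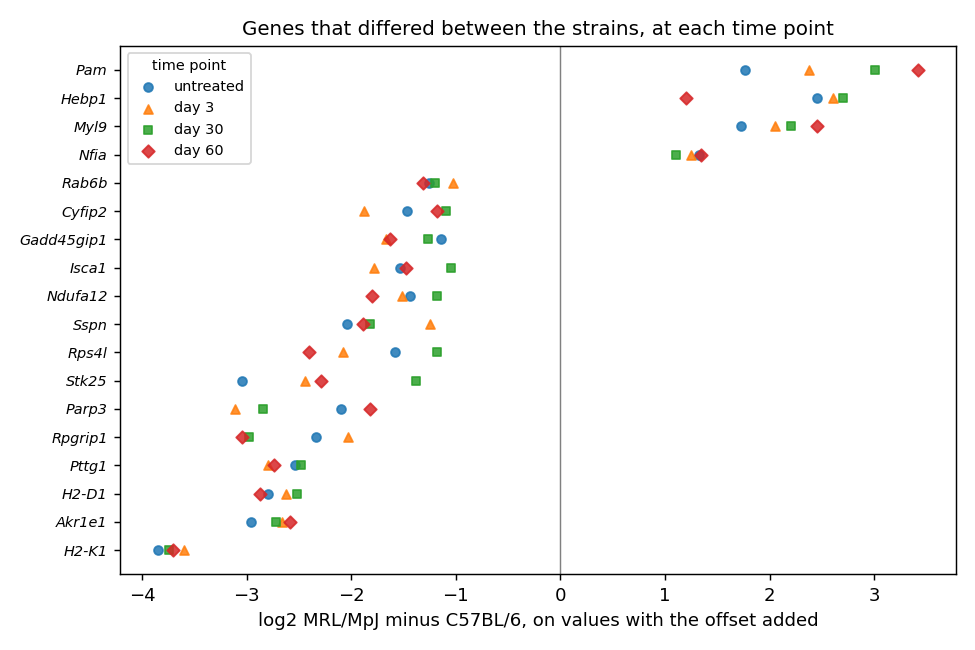
Difference MRL/MpJ minus C57BL/6 (log2 of values with the offset added) for the 18 genes that passed, with 1 point per time point, each from 1 array against 1. All points of the 4 upper genes lie above 0 and all points of the 14 lower genes lie below 0.

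Interferon-stimulated genes, which cells switch on against viruses, stood lower in MRL/MpJ. Of 17 measured members, 0 lay above 0 and the median log2 was -0.68 (-0.47 without either day 30 array); 10 were lower in MRL/MpJ when adjusted over the list alone, and 0 over all genes tested. Among these were Rsad2, an antiviral enzyme gene (log2 -1.25, SE 0.18), Oasl2 (-0.99) and Bst2, the tetherin gene (-1.04). The list for class II and antigen presentation had a median of -0.48 over 14 genes, with 6 lower when adjusted over the list alone and 2 over all genes tested. After H2-K1 and H2-D1 the largest were H2-Aa (log2 -1.60) and H2-Eb1 (-0.95), class II genes. Probe mismatch between the strains, taken up below, stays open for these H2 genes and so for part of this list's difference. Both lists passed limma's camera with adjusted p = 2.77e-10 and 1.27e-07, and both had adjusted p = 0.247 with an estimated correlation.

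Genes of the fetal and stress programme, which failing ventricles re-express, were higher in MRL/MpJ, with a median log2 of 0.36 over 18 genes and 14 above 0. Fhl1, a LIM protein gene (log2 1.13), Acta1, skeletal alpha-actin (1.07), and Fstl1, a secreted follistatin-like protein gene (0.99), were higher when adjusted over the list alone, 3 in all, with 0 over all genes tested. The list passed limma's camera (adjusted p = 0.000149), and had adjusted p = 0.452 with an estimated correlation. Without either untreated array its median was 0.61. Camera called 9 of the 33 lists for the strain difference, and 3 of them stayed called in every alternative with the preset correlation.

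Day 3 against untreated asks what the infarcted ventricle expresses in the early inflammatory phase, taking both strains together. Fibrillar collagen genes had the smallest p-values: Col1a1 stood at a log2 of 3.09 above untreated (SE 0.34, 2 arrays against 2), Col1a2 at 2.93 (SE 0.32) and Col3a1 at 2.44 (SE 0.26). Col1a1 signal was 646 in untreated and 3516 in day 3 C57BL/6, and 485.5 and 7072 in MRL/MpJ. Serpina3n, an acute-phase serine protease inhibitor gene, stood at 2.30 (SE 0.27) and Fn1, fibronectin, at 2.48 (SE 0.31). These 5 genes did not pass: limma called 0 of 8208 genes, with adjusted p = 0.0564 for the 3 collagen genes and 0.0640 and 0.0642 for Serpina3n and Fn1. The count depends on the processing: limma called 26 genes with an intensity trend, 14 with the filter on the mean signal and 12 with the larger offset. Col1a1, Col1a2, Col3a1 and Fn1 passed in these 3 of 15 alternatives and Serpina3n in 2. At an unadjusted p under 0.05 there were 537 genes, 372 of them higher, where chance gives 410.4.

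Of 32 measured genes for fibrillar collagen and matrix, 30 lay above untreated on day 3, with a median log2 of 1.40; 20 rose when adjusted over the list alone and 0 over all genes tested. Matricellular and wound genes had a median of 1.41 over 19 genes, and 11 rose when adjusted over the list alone, 0 over all genes tested. Examples were Postn, a matricellular protein of healing tissue (log2 3.09, SE 0.60), Tnc, tenascin C (2.27), and Timp1, an inhibitor of matrix proteases (2.19). Fibroblast markers had a median of 0.88 over 15 genes, and 10 rose when adjusted over the list alone, 0 over all genes tested. Matrix proteases such as Mmp2 (log2 1.62) and the cathepsin gene Ctsk (1.31) belong to a list with a median of 0.42 over 19 genes, of which 6 rose when adjusted over the list alone and 0 over all genes tested. These 4 lists passed limma's camera with adjusted p = 1.41e-24, 2.41e-13, 2.66e-10 and 1.43e-05, and each had adjusted p = 0.302 with an estimated correlation. Without the MRL/MpJ day 3 array the medians were 0.89 for matrix, 0.72 for matricellular genes and 0.21 for proteases; without the untreated MRL/MpJ array they were 0.90 for matricellular genes and 0.65 for proteases.

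All 30 measured macrophage and monocyte genes lay above untreated on day 3, with a median log2 of 0.81, and 14 rose when adjusted over the list alone, 0 over all genes tested. Gpnmb, a glycoprotein gene of lipid-laden macrophages, stood at 2.72 (SE 0.34), Mpeg1, a pore-forming protein gene, at 2.06 and Ctss, cathepsin S, at 1.84. Complement and coagulation genes had a median of 0.80 over 13 genes, and 6 rose when adjusted over the list alone, 0 over all genes tested; C1s1, a protease of the classical pathway, stood at 1.24. The list for class II and antigen presentation had a median of 0.56 over 14 genes, and the list of chemokines and cytokines 0.52 over 17 genes, with 0 members past the threshold in either when adjusted over the list alone and 0 over all genes tested. The 4 lists passed limma's camera with adjusted p = 5.55e-18, 6.79e-07, 1.03e-05 and 0.00147. They had adjusted p = 0.302 with an estimated correlation, except the chemokine list, which had adjusted p = 0.397 with an estimated correlation.

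Sfrp2, which encodes a secreted protein that binds Wnt ligands, stood at a log2 of 4.46 above untreated on day 3 (SE 0.62), with 893.6 in C57BL/6 and 3143 in MRL/MpJ against 46.8 and 51.3 in untreated hearts. It and Dkk3 (log2 1.81) rose when adjusted over the list alone, 2 of 12 genes in the Wnt list, with 0 over all genes tested and a list median of 0.46. Dkk3 is also a member of the list of atrial and conduction markers. Heat shock genes lay lower: 3 of 20 fell when adjusted over the list alone, 0 over all genes tested, namely Hspa1b (log2 -2.61, SE 0.33), Hspa1a (-1.89) and Dnajb1 (-0.97), chaperone genes induced by stress, and the list median was -0.20. The Wnt and heat shock lists passed limma's camera with adjusted p = 0.000116 and 0.00147, and each had adjusted p = 0.302 with an estimated correlation. Genes of oxidative phosphorylation and the TCA cycle, which make most of the heart's ATP, had a median of -0.31 over 49 genes, of which 45 lay below untreated and 0 passed when adjusted over the list alone or over all genes tested. That list passed limma's camera with adjusted p = 5.08e-08, and had adjusted p = 0.474 with an estimated correlation.

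Without the untreated MRL/MpJ array, the day 3 medians were 0.70 for the Wnt list, -0.37 for heat shock and -0.16 for oxidative phosphorylation; without the untreated C57BL/6 array they were -0.09 for heat shock and -0.49 for oxidative phosphorylation. Oxidative phosphorylation had a median of -0.52 without the C57BL/6 day 3 array and -0.15 without the MRL/MpJ day 3 array. Fatty acid oxidation genes, the main fuel pathway of the adult heart, had a median log2 of -0.47 over 26 genes on day 3 (limma's camera, adjusted p = 1.71e-06; adjusted p = 0.474 with an estimated correlation). Ion channel and coupling genes had a median of -0.37 over 17 genes (limma's camera, adjusted p = 3.05e-05; adjusted p = 0.345 with an estimated correlation). Both calls ended without the MRL/MpJ day 3 array, with medians of -0.08 and -0.12; without the C57BL/6 day 3 array they were -0.75 and -0.58. Camera called 19 lists on day 3, and 11 stayed called in every alternative with the preset correlation.

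**Figure D2:**
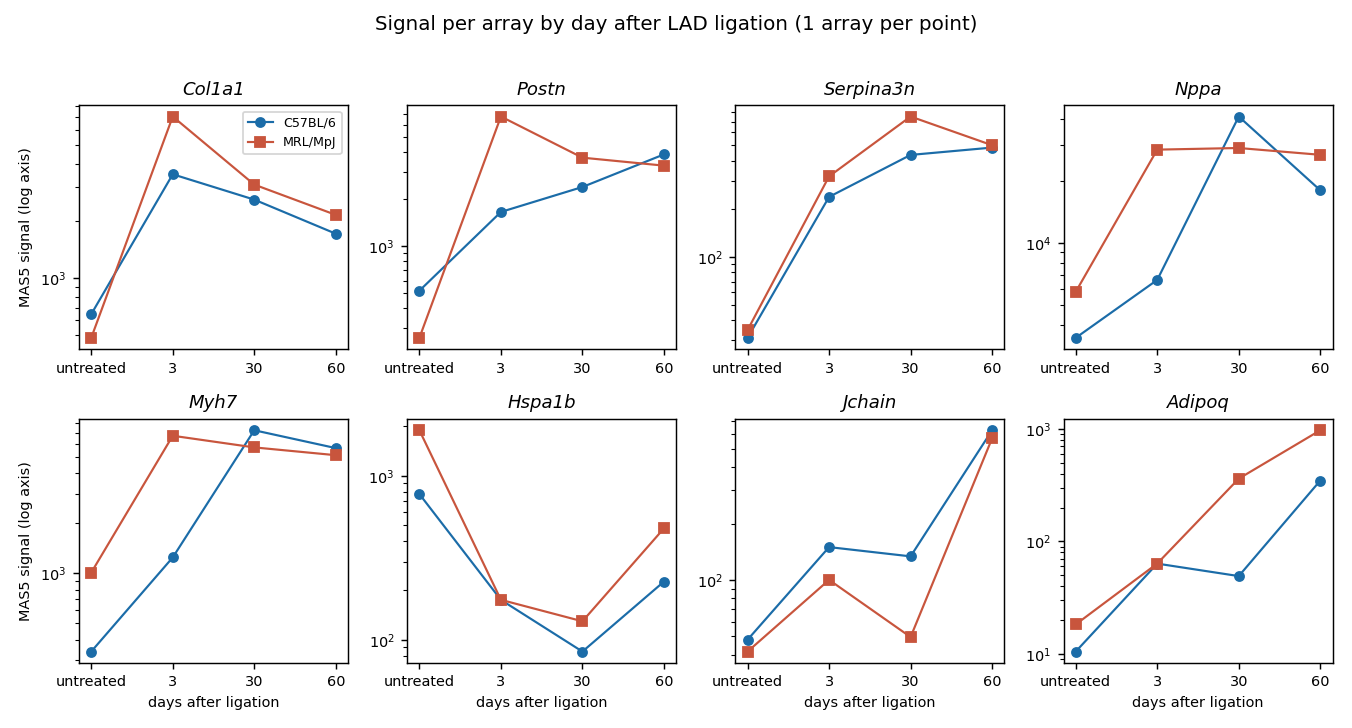
MAS5 signal (log axis) of 8 genes in each array by days after ligation, with circles for C57BL/6 and squares for MRL/MpJ, 1 array per point. Signals of Col1a1, Postn, Serpina3n, Nppa and Myh7 lie above the untreated array of the same strain in all 6 ligated arrays, those of Hspa1b lie below it, and Jchain and Adipoq have their highest signals on day 60.

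Day 30 against untreated asks what the ventricle expresses once a scar has formed. Serpina3n, the acute-phase inhibitor gene, rose by a log2 of 3.29 (SE 0.27, 2 arrays against 2), from signals of 31.1 and 34.8 in untreated C57BL/6 and MRL/MpJ to 434 and 755 on day 30. Among genes of the fetal and stress programme, the stress hormone gene Nppa rose when adjusted over the list alone (log2 2.94, SE 0.52). So did the slow myosin heavy chain gene Myh7 (3.39, SE 0.63) and the connective tissue growth factor gene Ccn2 (2.16). In all 6 of 18 rose and 1 fell when adjusted over that list alone, 0 over all genes tested, with a median of 0.73 and 15 above 0. Myl7 and Myl4, atrial light chain genes of that list, stood at 2.83 (SE 1.73) and 2.66 (SE 1.36) and did not pass. The list of atrial and conduction markers, which shares Nppa, Myl4 and Myl7 with the fetal list, had a median of 1.71 over 10 genes, with 2 risen when adjusted over the list alone and 0 over all genes tested. It passed limma's camera (adjusted p = 0.00338), and had adjusted p = 0.361 with an estimated correlation; the call ended without the MRL/MpJ day 30 array (median 2.21). Serpina3n was the 1 gene of 8208 that limma called (adjusted p = 0.0196), higher in both strains; 905 genes had an unadjusted p under 0.05. The C57BL/6 day 30 array correlated less with the others than they did among themselves (r at most 0.877), and the count was 1 without it. The count was 186, 72 higher and 114 lower, without the MRL/MpJ day 30 array; it was 0 without either untreated or either day 60 array and 2 without either day 3 array.

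Matrix genes on day 30 had a median log2 of 0.98 over 32 genes, and 20 rose when adjusted over the list alone, 0 over all genes tested; Col1a1 stood at 2.28. All 19 matricellular and wound genes lay above untreated with a median of 1.10, and 10 rose when adjusted over the list alone, 0 over all genes tested, among them Comp, a cartilage matrix protein gene (log2 3.00), and Postn (2.92). Fibroblast markers had a median of 0.86 and matrix proteases one of 0.57, with 7 of 15 and 7 of 19 genes past the threshold when adjusted over the list alone, 0 over all genes tested. Complement and coagulation genes had a median of 0.64 over 13 genes; 6 rose when adjusted over the list alone, and 1, Serpina3n, over all genes tested. The fetal, matricellular, protease, fibroblast and complement lists passed limma's camera with adjusted p = 2.80e-06, 6.55e-12, 0.000210, 9.01e-10 and 1.46e-06, and each had adjusted p = 0.361 with an estimated correlation. The matrix list passed with adjusted p = 8.17e-13 in limma's camera, and had adjusted p = 0.398 with an estimated correlation. Without the C57BL/6 day 30 array, which stood apart from the others, the medians were 0.50 for fibroblast markers and 0.24 for proteases; without the untreated MRL/MpJ array the complement median was 0.39.

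Of 30 macrophage and monocyte genes, 28 lay above untreated on day 30 (median log2 0.72), and 0 passed when adjusted over the list alone or over all genes tested. B cell and immunoglobulin genes had a median of 0.65, with 9 of 9 above 0 and 0 past the threshold when adjusted over the list alone or over all genes tested. Sfrp2 (log2 3.78) and Dkk3 (2.72), the latter also in the atrial list, rose in the Wnt list when adjusted over the list alone. Hspa1b (-3.21), Hspa1a (-1.93) and Dnajb1 (-1.12) fell in the heat shock list in the same way, with 0 over all genes tested in either list. The medians of the Wnt and heat shock lists were 0.41 and -0.30. The macrophage, heat shock and Wnt lists passed limma's camera with adjusted p = 1.07e-09, 0.00338 and 0.000778, and had adjusted p = 0.361 with an estimated correlation. The B cell list passed with adjusted p = 0.000166 in limma's camera, and had adjusted p = 0.378 with an estimated correlation. Without the C57BL/6 day 30 array, which stood apart, the B cell median was 0.25; it was 1.08 without the MRL/MpJ day 30 array and 0.41 without the untreated C57BL/6 array. The macrophage median was 0.39 without the untreated MRL/MpJ array, and the Wnt median was 0.66 without the MRL/MpJ day 30 array. Camera called 18 lists on day 30, and 10 stayed called in every alternative with the preset correlation.

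Day 60 against untreated asks what remains in the late remodelled ventricle. The antibody light chain gene Igkv8-30 rose by a log2 of 3.41 (SE 0.32, 2 arrays against 2) and Jchain, which joins secreted IgM and IgA, by 3.10 (SE 0.29). Jchain signals were 48 and 41.5 in untreated C57BL/6 and MRL/MpJ and 628.6 and 569 on day 60. Serpina3n rose by 3.08 (SE 0.27). In limma 3 of 8208 genes passed, all higher in both strains and each with adjusted p = 0.0211; 866 genes had an unadjusted p under 0.05. The count was 0 without either untreated or either day 60 array, 30 without either day 3 array and 12 without either day 30 array.

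In the B cell list, 3 of 9 genes rose on day 60 when adjusted over the list alone, and 1, Jchain, over all genes tested; the other ones were Ighm, the IgM heavy chain gene (log2 3.42), and the light chain gene Iglv1 (2.73). The B cell surface genes Cd79a (log2 -0.12) and Blk (-0.31) did not pass, and the list median was 0.11 with a mean of 1.05. The list passed limma's camera (adjusted p = 0.00123), and had adjusted p = 0.386 with an estimated correlation. Its median was 0.34 without the untreated C57BL/6 array, 0.06 without the untreated MRL/MpJ array, 0.21 without the C57BL/6 day 60 array and 0.36 without the MRL/MpJ day 60 array. Among 8 adipocyte genes, Adipoq, the adiponectin gene (log2 3.84, SE 0.52), Car3, a carbonic anhydrase gene abundant in fat (3.64), and Scd1, a fatty acid desaturase gene (2.48), rose when adjusted over the list alone, with 0 over all genes tested. Adipoq signal went from 10.5 to 347 in C57BL/6 and from 18.3 to 972.5 in MRL/MpJ. The adipocyte list, with a median of 0.38, passed limma's camera (adjusted p = 0.000140), and had adjusted p = 0.281 with an estimated correlation.

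Matrix genes on day 60 had a median log2 of 1.15 over 32 genes, and 22 rose when adjusted over the list alone, 0 over all genes tested. Matricellular and wound genes had a median of 1.28 over 19 genes, and 13 rose when adjusted over the list alone, 0 over all genes tested; Comp stood at 4.15 (SE 0.57), Postn at 3.18 and Ccn2 at 2.55. Fibroblast markers had a median of 1.03 (10 of 15 genes rose when adjusted over the list alone) and matrix proteases 0.49 (6 of 19), with 0 over all genes tested in either. All 13 complement and coagulation genes lay above untreated, with a median of 0.86; 7 rose when adjusted over the list alone and 1 over all genes tested, and C1s1 stood at 2.28. Genes of TGF-beta and BMP signalling had a median of 0.49 over 18 genes, and Ltbp2, Bmp4 and Tgfbi (log2 2.50, 1.18 and 1.17) rose when adjusted over the list alone, 0 over all genes tested. These 6 lists passed limma's camera with adjusted p = 3.75e-19, 6.88e-18, 9.59e-13, 4.64e-06, 4.69e-11 and 4.70e-06, and each had adjusted p = 0.281 with an estimated correlation. The TGF-beta median was 0.26 without the untreated MRL/MpJ array and 0.30 without the MRL/MpJ day 60 array.

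In the fetal and stress programme, 5 of 18 genes rose on day 60 when adjusted over the list alone and 0 over all genes tested, among them Myh7 (log2 3.14) and Nppa (2.29), and the median was 0.63. Macrophage and monocyte genes had a median of 0.68 over 30 genes, and 6 rose when adjusted over the list alone, 0 over all genes tested. Immediate early genes, which encode transcription factors and regulators induced within minutes of a stimulus, had a median of 0.48 over 17 genes; 1, Ier3 (log2 1.49), rose when adjusted over the list alone, 0 over all genes tested. The fetal, macrophage and immediate early lists passed limma's camera with adjusted p = 6.81e-05, 1.16e-11 and 0.000111, and each had adjusted p = 0.281 with an estimated correlation. Of 26 fatty acid oxidation genes, 25 lay below untreated (median -0.55), with 0 past the threshold when adjusted over the list alone or over all genes tested; Mlycd, malonyl-CoA decarboxylase, stood at -1.16 and Cpt2, a carnitine palmitoyltransferase gene, at -1.05. That list passed limma's camera (adjusted p = 9.90e-06), and had adjusted p = 0.447 with an estimated correlation. The medians were 0.37 for the fetal list and 0.41 for macrophages without the untreated MRL/MpJ array, and 0.32 for immediate early genes without the MRL/MpJ day 60 array. Camera called 18 lists on day 60, and 12 stayed called in every alternative with the preset correlation.

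Changes between the ligated days compare 2 arrays with 2, with the spread taken from the model of all 8 arrays. From day 3 to day 30 matrix genes had a median log2 of -0.32 over 32 genes, with Eln, the elastin gene, at -1.30, and genes of the fetal and stress programme a median of 0.43 over 18 genes, with the atrial myosin light chains Myl7 at 3.29 (SE 1.73) and Myl4 at 2.71 (SE 1.36) and Nppa at 1.33. Both passed limma's camera with adjusted p = 0.000441 and 0.000327; they had adjusted p = 0.934 and 0.871 with an estimated correlation. The matrix median was 0.08 without the MRL/MpJ day 3 array and -0.19, no longer called, without the MRL/MpJ day 30 array, and the fetal list was not called without the latter (median 0.34). Without the C57BL/6 day 3 array the medians were -0.94 and 0.15, and without the C57BL/6 day 30 array the matrix median was -0.67. Atrial and conduction markers, which share Myl7, Myl4 and Nppa with the fetal list, had a median of 0.94 over 10 genes (limma's camera, adjusted p = 0.00691; adjusted p = 0.871 with an estimated correlation). That call ended without the MRL/MpJ day 3 array (0.68), the C57BL/6 day 30 array (0.50) or the MRL/MpJ day 30 array (1.61), and the median was 0.43 without the C57BL/6 day 3 array. Camera called 8 lists, and 0 stayed called in every alternative with the preset correlation. It called 0 lists without the MRL/MpJ day 30 array and 4 without the MRL/MpJ day 3 array. The latter include lists not called with all arrays. Without that array the calls for sarcomere, matrix, class II and antigen presentation, oxidative phosphorylation, glycolysis, atrial and adipocyte lists ended. In limma 0 of 8208 genes passed (smallest adjusted p = 0.292), with 470 at an unadjusted p under 0.05; those with the smallest p were Arfgap3 (log2 -1.93), Zmynd8 (-1.97), Ppp1r12c (2.00), Ift46 (1.61) and Csn2 (-1.67).

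From day 30 to day 60 the 17 immediate early genes had a median log2 of 0.29, with Fos at 1.03 and Nr4a1 at 0.85, and this was the 1 list called (limma's camera, adjusted p = 0.0279; adjusted p = 0.931 with an estimated correlation). The call ended without the MRL/MpJ day 30 array (median 0.12), without the MRL/MpJ day 60 array (0.21) and after quantile normalization (0.25); the median was 0.48, still called, without the C57BL/6 day 30 array, which stood apart from the others. Camera called 0 lists without the MRL/MpJ day 30 array, 13 without the C57BL/6 day 30 array and 9 without the C57BL/6 day 60 array. In limma 0 of 8208 genes passed, with 659 at an unadjusted p under 0.05. Arfgap3, a GTPase-activating protein gene of the Golgi (log2 2.40, SE 0.23), had the smallest adjusted p = 0.0703 in limma, followed by Jchain (2.48), Nup54 (1.96), Prss39 (-2.25) and Ifna5 (-2.07).

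The interaction terms ask whether the hearts of the strains responded differently to ligation. On day 3 matrix genes were higher in MRL/MpJ relative to the other time points, with a median log2 interaction of 0.80 over 32 genes and 31 above 0. Matricellular and wound genes had a median of 0.99 over 19 genes, with Postn at 2.19, and fibroblast markers one of 0.48 over 15 genes. Fatty acid oxidation genes had a median of -0.59 over 26 genes, with 25 below 0 and Pdk4, a kinase gene that restrains glucose oxidation, at -2.60. Ion channel and coupling genes had a median of -0.71 over 17 genes, with the potassium channel gene Kcna5 at -1.96, and oxidative phosphorylation genes one of -0.32 over 49 genes. Adjusted over the list alone, 2 matrix genes passed (Col12a1, 3.74, and Fmod, 2.31), 1 ion channel gene (Kcna5) and 0 genes of the other 4 lists, with 0 over all genes tested.

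The matrix, matricellular, fibroblast, fatty acid oxidation, oxidative phosphorylation and ion channel lists passed limma's camera for this term with adjusted p = 2.18e-10, 1.42e-06, 0.00556, 8.88e-08, 0.000123 and 0.000123. The matricellular, fibroblast and ion channel lists had adjusted p = 0.797 with an estimated correlation, and the other 3 had adjusted p = 0.832 with an estimated correlation. The ion channel median was -0.41 without either untreated array, and the oxidative phosphorylation median was -0.18 without either day 30 array. In limma 0 of 8208 genes passed the day 3 term (smallest adjusted p = 0.637; 418 at an unadjusted p under 0.05), and 3 passed without either untreated array. The genes with the smallest p were Acot3, an acyl-CoA thioesterase gene (log2 3.95, SE 0.55), Klf15, a transcription factor of cardiac metabolism (-2.99), the collagen gene Col12a1 (3.74), Tmem214 (2.56; another probe set gave -0.30) and Fosl1, of the AP-1 family (2.65). Camera called 8 lists for this term, and 6 stayed called in every alternative with the preset correlation.

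Set against the untreated pair, the ligated MRL/MpJ hearts had higher matrix genes (median log2 interaction 0.62 over 32 genes, 30 above 0) and macrophage genes (0.49 over 30 genes, 28 above 0) than the ligated C57BL/6 hearts. Examples were Vcan, versican (1.25), Col6a3 (1.24) and the macrophage genes Ms4a6d (2.10) and Lyz2, lysozyme (1.27), and 0 members of either list passed when adjusted over the list alone or over all genes tested. These lists passed limma's camera with adjusted p = 7.97e-08 and 3.53e-07, and each had adjusted p = 0.884 with an estimated correlation. The matrix median was 0.33 without either day 3 array. This term pools the ligated days, and the matrix difference was not seen on each: on day 30 the list's changes from untreated were nearly equal in both strains, as given below. Camera called 8 lists for this term, 5 without either day 3 array and 4 without either day 60 array. Of the 8, 2 stayed called in every alternative with the preset correlation. In limma 0 of 8208 genes passed, with 167 at an unadjusted p under 0.05, fewer than the 410.4 that chance gives. The genes with the smallest p were Crybb2 (log2 -2.71), Tlr9 (-3.13), Tarbp2 (2.60), Ccdc43 (-2.45) and Abca2 (3.06).

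**Figure D3:**
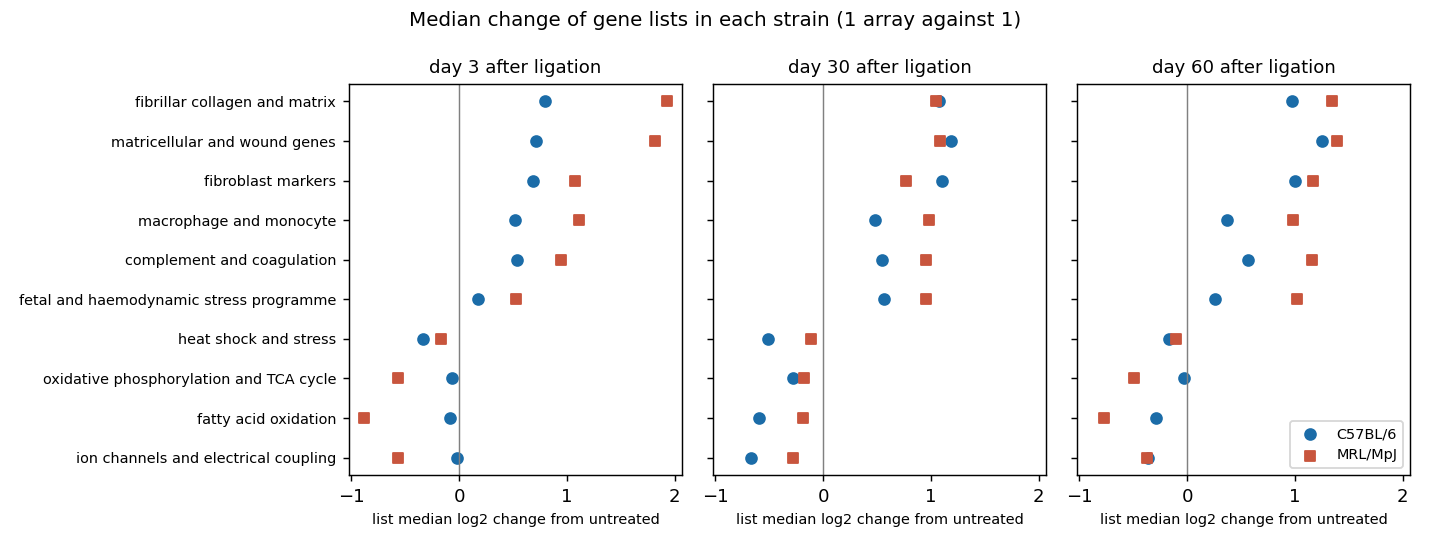
Median log2 change from the untreated array of the same strain for 10 gene lists on days 3, 30 and 60, with circles for C57BL/6 and squares for MRL/MpJ, each from 1 array against 1. On day 3 the matrix list has a median of 0.79 in C57BL/6 and 1.93 in MRL/MpJ, and the fatty acid oxidation list one of -0.09 and -0.88.

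Within each strain, changes from untreated were counted without a test. On day 3 the matrix list had a median log2 change of 0.79 in C57BL/6 and 1.93 in MRL/MpJ, and macrophage genes 0.52 and 1.11. Each of these 4 medians stood at percentile 100 among 10000 random lists matched on signal. The percentile is a description: it holds no spread between animals, and genes of a list can vary together, unlike those of random lists. On day 30 the matrix medians were 1.08 and 1.05, and on day 60 they were 0.98 and 1.35. Genes changed at least 2-fold numbered 310 in C57BL/6 and 629 in MRL/MpJ on day 3, 1225 and 461 on day 30, and 472 and 608 on day 60. The C57BL/6 day 30 array, which has the highest of these counts, is the one that stood apart from the others. Higher in both strains were 85 genes on day 3, 111 on day 30 and 151 on day 60, where chance overlap gives 9.96, 20.2 and 13.6; lower in both were 8, 45 and 31, where chance gives 2.95, 14.4 and 4.96. Opposite directions were taken by 25, 31 and 17 genes, where chance gives 10.8, 34.2 and 16.4. Across genes, which are not independent replicates, the changes in C57BL/6 and MRL/MpJ correlated with r = 0.271 on day 3, 0.249 on day 30 and 0.485 on day 60. Between different days r ranged from 0.232 to 0.411, the highest for C57BL/6 on day 30 with MRL/MpJ on day 3. For 2730 genes with at least 2 probe sets, the changes of the 2 brightest were compared. They correlated with r = 0.254, 0.304 and 0.377 in C57BL/6 on days 3, 30 and 60, and 0.524, 0.352 and 0.546 in MRL/MpJ. The counts and correlations above thus depend in part on which probe set stands for a gene.

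**Figure D4:**
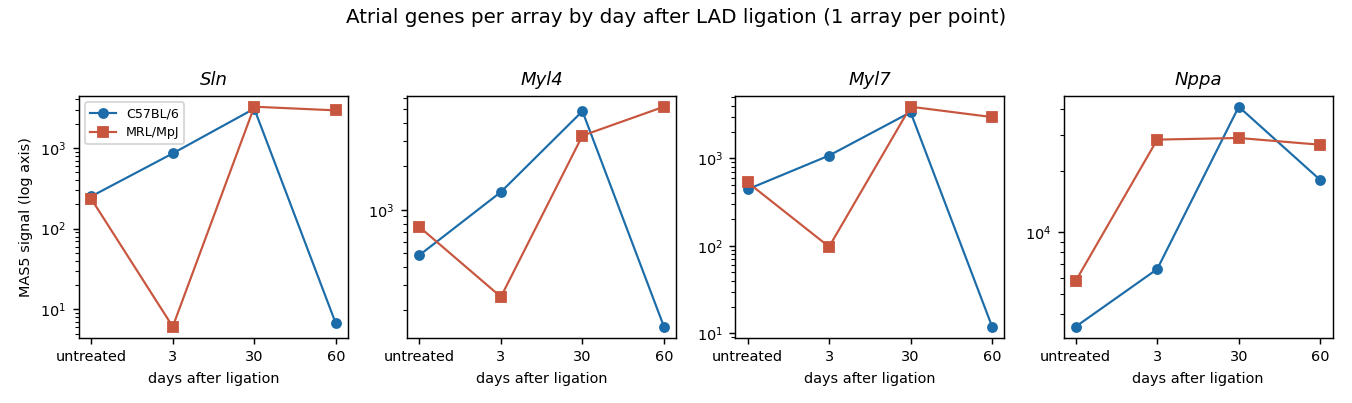
MAS5 signal (log axis) of Sln, Myl4, Myl7 and Nppa in each array by days after ligation, with circles for C57BL/6 and squares for MRL/MpJ, 1 array per point. Sln, Myl4 and Myl7 lie lowest in MRL/MpJ on day 3 and in C57BL/6 on day 60, while Nppa lies above the untreated array of the same strain in all 6 ligated arrays.

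Sln, which encodes the calcium pump regulator sarcolipin, and Myl4 and Myl7, the atrial myosin light chains, differed between the strains in opposite directions on days 3 and 60. On day 3 Myl7 signal was 1078 in C57BL/6 and 97.6 in MRL/MpJ, and on day 60 it was 11.9 and 2967, against 442 and 532.5 in untreated hearts. Sln changed by a log2 of 1.66 in C57BL/6 and -2.92 in MRL/MpJ on day 3, and by -2.99 and 3.49 on day 60. Nppa was above untreated in all 6 ligated arrays, from 6605 in C57BL/6 on day 3 to 41056 in C57BL/6 on day 30. These are values of 1 array against 1; in the day 3 interaction Sln, Myl4 and Myl7 did not pass (limma, adjusted p = 0.931).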

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

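The tests of the tissue taken (injured tissue in the MRL/MpJ day 3 piece, and atrial tissue for Sln, Myl4 and Myl7 and for Nppa) were chosen only after the result was seen. The interaction tests were planned before the data were examined. For the splits of the arrays, the other probe sets and quantile normalization, predictions were written before these tests were run. They address patterns already seen in the results, such as the strain calls.

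Most strain calls were lower in MRL/MpJ (14 of 18), H2-K1 and H2-D1 among them. Swapping strains within time points gives 8 splits, too few for a share under 0.05. The real split gave 18 calls and the highest of the others 0. Without the time block 1 of the 35 splits into 4 and 4 arrays, the real one, gave as many as 27 calls (highest other 3). That share is under 0.05 and is the smallest that 35 splits can give. It argues against chance for the 27 calls, while the swaps cannot decide for the 18 calls with the time block. A candidate explanation is probes that match C57BL/6 sequence better than MRL/MpJ sequence, since these strains carry different H2 haplotypes: over the 7 called genes with another probe set, the median ratio of the others' difference to the called one's was 0.424 (interquartile range 0.193), where under 0.25 was predicted for mismatch and over 0.75 without it. The same ratio was 0.477 for the 50 genes with the smallest p for strain, 0.762 for day 3, 0.453 for day 30 and 0.769 for day 60. In the day 30 comparison each side holds both strains, so a ratio this low can arise without mismatch between strains. The limits therefore separate the explanations poorly. For H2-D1 the ratio of 0.424 averages 5 other probe sets that ran from -3.07 to 2.56. The genes differ: the ratio was 1.25 for Pttg1, over 0.75, and 0.067 for Isca1 and 0.204 for Parp3, under 0.25, with the other 4 between these limits, so probe mismatch and a strain difference in expression cannot be told apart for the called genes as a group.

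Matrix and wound genes differed more from untreated on day 3 in MRL/MpJ than in C57BL/6. A difference in the signal distribution of the day 3 arrays is argued against: after quantile normalization the median interaction of the matrix list was 0.86, against 0.80 as deposited. More injured tissue in the MRL/MpJ day 3 piece may account for it, since fibroblast and macrophage lists were higher too (0.48 and 0.44) and ion channel and fatty acid oxidation lists lower (-0.71 and -0.59), but the sarcomere list was near 0 (-0.057). This and a difference between the strains in the response itself cannot be told apart with 1 array per strain and day. The strain response stays open as an untested biological explanation.

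Sln, Myl4 and Myl7 moved together between arrays: Sln and Myl7 log2 signals had Pearson r = 0.979 (exact permutation p = 0.000322, adjusted 0.000645) and Spearman rho = 0.952 (exact p = 0.00114, adjusted 0.00456) over the 8 arrays, and r = 0.993 without MRL/MpJ day 3 and C57BL/6 day 60, among 4 pairs of genes tested. Varying amounts of atrial tissue in the piece taken may be the source, since these genes are atrial markers. The genes were picked because they vary between these same arrays, so their correlation and its p-values are no independent support. The tables argue against atrial tissue as the whole source of Nppa above untreated in all 6 ligated hearts: in the 2 ligated arrays with Myl7 below untreated, Nppa was still at least 4.91-fold its untreated signal. The other 4 ligated arrays (C57BL/6 day 3, MRL/MpJ day 60 and both of day 30) had Myl7 above untreated, so atrial tissue stays open there as a part of the Nppa signal. Nppa and Myl7 had r = 0.223 (exact permutation p = 0.586, adjusted 0.586) and rho = 0.524 (exact p = 0.197, adjusted 0.197), with r = 0.215 without both untreated arrays.

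The test of a difference between the strains' responses singled out these lists, given as medians of the interaction; none passed with an estimated correlation. For the ligated pairs against the untreated pair they were 0.62 for matrix, 0.53 for matricellular genes, 0.49 for macrophages, 0.43 for the fetal programme, 0.39 for complement, -0.24 for oxidative phosphorylation, -0.27 for the sarcomere and -0.47 for skeletal muscle. For day 3 they were 0.99 for matricellular genes, 0.80 for matrix, 0.53 for B cells, 0.48 for fibroblasts, 0.44 for macrophages, -0.32 for oxidative phosphorylation, -0.59 for fatty acid oxidation and -0.71 for ion channels. Without either day 3 array the calls for the sarcomere (-0.25), matricellular genes (0.20), complement (0.32) and oxidative phosphorylation (-0.16) in the ligated pairs ended, and the matrix median was 0.33. Quantile normalization ended those for the sarcomere (0.0036), oxidative phosphorylation (-0.17) and skeletal muscle (-0.38). Without either day 60 array those for the sarcomere (-0.22), the fetal programme (0.20), complement (0.45), oxidative phosphorylation (-0.16) and skeletal muscle (-0.40) ended, and without either day 30 array that for skeletal muscle (-0.57), while the oxidative phosphorylation median was -0.46. For day 3, the macrophage call ended without either untreated array (0.31), where the ion channel median was -0.41, and the B cell call ended after quantile normalization (0.39) and without either day 30 array (0.45), where the oxidative phosphorylation median was -0.18.

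Other genes differed from untreated at least 2-fold in opposite directions in the strains. This difference from the untreated pair was not tested, with 1 array on each side. All days use the same untreated array of each strain. Genes that recur with the same sign, such as Lao1, Frs3, Carns1 and Crybb2 on days 3 and 60, are therefore not independent findings on each day. The day 3 interaction, which sets the day 3 pair against all other pairs, was tested in limma, and 0 of the genes named for day 3 passed (lowest adjusted p = 0.637). The MRL/MpJ change minus the C57BL/6 change (log2) on day 3 was 4.29 for Acot3, 3.86 for Tcp11, 3.81 for Abca2, 3.53 for Npy, 3.38 for Col12a1, 3.11 for Lao1, 3.02 for Exosc5 and 3.01 for Tarbp2. It was -4.59 for Sln, -3.91 for Frs3, -3.39 for Myl7, -3.34 for Carns1, -3.18 for Terf2, -3.01 for Crybb2, -2.92 for Myl4 and -2.64 for Nifk. On day 30 it was 3.30 for Pcyt2, 3.28 for Ptprcap, 3.04 for Htra2, 2.88 for Tmem63a and 2.77 for Tmem176a. It was -3.87 for Tlx2, -3.55 for Slc17a9, -3.50 for Capn5, -3.46 for Nusap1, -3.43 for Blm, -3.42 for Lrrc23, -3.30 for Nr5a1 and -3.30 for Cadm3 on that day, which rests on the C57BL/6 array that correlated least with the others. On day 60 it was 6.48 for Sln, 5.96 for Myl7, 4.22 for Myl4, 3.47 for Lao1 and 2.60 for Nt5e. It was -4.39 for Frs3, -3.23 for Tlr9, -3.13 for Tom1l1, -2.93 for Mylpf, -2.82 for Zdhhc6, -2.74 for Kcnk4, -2.74 for Carns1 and -2.58 for Crybb2.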

How the results depend on the processing

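All tests in this part were planned before the data were examined. No paired analysis was possible because the labels number no animals; arrays were blocked by time point and strain only. Over the alternatives, named genes kept direction and side of the threshold in 535 of 639 cases, no longer passed in 85, newly passed in 19 and reversed in 0. Under quantile normalization, centring and leaving out each array, with the preset correlation, called lists stayed called in 738 of 858 cases, were lost in 114 and turned in 6: on day 30 without the C57BL/6 day 30 array, fatty acid oxidation (0.033) and oxidative phosphorylation (-0.054, where the median and the test differ in sign); for day 30 against day 3, matrix (0.085) and oxidative phosphorylation (-0.053) without the MRL/MpJ day 3 array, and oxidative phosphorylation (-0.12) and glycolysis (-0.017) without the MRL/MpJ day 30 array. With each array left out in turn these medians ranged, on day 30, from -0.82 to 0.033 for fatty acid oxidation and from -0.45 to -0.016 for oxidative phosphorylation, and for day 30 against day 3 from -0.94 to 0.085 for matrix, -0.12 to 0.30 for oxidative phosphorylation and -0.017 to 0.42 for glycolysis. The cause was not tested. Where a comparison does not set the time point of the array left out against another, leaving out either array of that pair gives the same fit. This holds for strain and both interactions, so the 639 and 858 cases include repeated fits.

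Leaving out each array in turn, calls of limma (18 with all arrays for strain, 0 for day 3, 1 for day 30, 3 for day 60, 0 for each of the other comparisons) ranged from 7 to 14 for strain, 0 to 0 for day 3, 0 to 186 for day 30, 0 to 30 for day 60, 0 to 0 for day 30 against day 3 and for day 60 against day 30, 0 to 3 for the day 3 interaction and 0 to 0 for the ligation interaction. In comparisons of days that use the time point of the array left out, the lone array there was assumed to vary like the others. In the other comparisons the lone array added nothing to the fit. The 186 calls came without MRL/MpJ day 30, the 30 without either day 3 array, and both the 7 for strain and the 3 for the day 3 interaction without either untreated array. Called lists ranged from 8 to 10 for strain, 15 to 20 for day 3, 14 to 20 for day 30, 17 to 20 for day 60, 0 to 11 for day 30 against day 3, 0 to 13 for day 60 against day 30, 4 to 12 for the ligation interaction and 7 to 9 for the day 3 interaction. An estimated correlation, not counted in the 858 cases, ended every list call: 0 lists were called in any comparison. With it camera also called 0 of 4 simulated lists that had been shifted by a log2 of 0.5. These failures therefore cannot decide whether the list calls rest on genes that vary together. Quantile normalization gave 3 lists for day 30 against day 3, 0 for day 60 against day 30 and 5 for the ligation interaction.

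Calls moved by over 1.5 times as follows. With an intensity trend there were 43 for strain, 26 for day 3, 24 for day 30 and 75 for day 60. The filter on the mean signal gave 29, 14, 6 and 25, and an offset 4 times larger 31, 12, 7 and 41, with 1 for day 60 against day 30. An offset 4 times smaller gave 11 for strain and 1 for day 60, no filter 8 for strain and 0 for days 30 and 60, all probe sets 56 for strain, 2 for day 3 and 18 for day 60, centring on medians 5 for day 60, and leaving out both day 3 arrays 8 for strain. No filter and all probe sets test more features; the cause of the other shifts was not tested.

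Counts past the fold limit (C57BL/6, MRL/MpJ, both) depend on signal over background. At 3-fold they were 84, 198 and 24 on day 3, 337, 109 and 38 on day 30, and 130, 171 and 51 on day 60. The larger offset gave 82, 288 and 32, then 491, 143 and 59, then 162, 257 and 83. All probe sets gave 560, 1069 and 154, then 2111, 793 and 254, then 841, 986 and 300. Without a filter they were 747 and 1044 on day 3, 2108 and 860 on day 30, and 954 and 1013 on day 60 in C57BL/6 and MRL/MpJ. The filter on the mean gave 170 and 308 in C57BL/6 on days 3 and 60 and 287 in MRL/MpJ on day 30. The correlation between the strains' changes was 0.330, 0.286 and 0.529 on days 3, 30 and 60 with the filter on the mean, and 0.321, 0.294 and 0.530 with the larger offset.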

Other observations

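The results here come from lists and tests planned before the data were examined, apart from Cyp2e1, which was chosen after its values were seen. Genes of the circadian clock had a median log2 of 0.35 over 13 genes on day 60 against untreated, and they moved apart: Dbp, a clock-driven transcription factor gene, rose (1.51) and Arntl, which encodes the core clock activator BMAL1, fell (-1.13) when adjusted over the list alone, with 0 over all genes tested. The list passed limma's camera (adjusted p = 0.0162), and had adjusted p = 0.281 with an estimated correlation; the call ended without the untreated C57BL/6 array (median 0.23) and without the C57BL/6 day 60 array (0.48). The hour of day at which hearts were taken is not in the labels. Cyp2e1, a cytochrome P450 gene, stood at a log2 of 1.85 on day 60 (SE 0.26) and did not pass in limma (adjusted p = 0.0619).

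Several lists that matter in an injured heart did not pass limma's camera on any day against untreated with all 8 arrays, though some did with 1 array left out. Cell cycle and proliferation genes had medians of 0.19, 0.18 and 0.09 over 22 genes on days 3, 30 and 60, with adjusted p = 0.0887, 0.288 and 0.127 in limma's camera. Cdk1, the mitotic kinase gene, stood at 1.01, 1.22 and 1.23. Neutrophil genes had medians of 0.16, -0.10 and -0.23 over 9 genes, T and NK cell genes 0.24, -0.10 and -0.57 over 5, endothelial genes -0.13, -0.06 and -0.01 over 21, and sarcomere genes -0.08, 0.15 and -0.04 over 28. Smooth muscle and myofibroblast genes had medians of 0.23, 0.23 and 0.25 over 13 genes.

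With 1 array left out, cell cycle genes passed limma's camera on day 3 without the untreated MRL/MpJ array (median log2 0.37), on day 30 without the MRL/MpJ day 30 array (0.41), and on day 60 without the untreated MRL/MpJ array (0.17) or the C57BL/6 day 60 array (0.096). Their day 30 median was -0.12 without the C57BL/6 day 30 array, which stood apart from the others. T and NK cell genes passed on day 30 without the C57BL/6 day 30 array (-0.77) and on day 60 without the MRL/MpJ day 60 array (-0.48); their medians were 0.50 on day 30 without the MRL/MpJ day 30 array and 0.027 on day 60 without the C57BL/6 day 60 array. Sarcomere genes passed on day 3 without the untreated C57BL/6 array (-0.21) and on day 30 without the untreated MRL/MpJ array (0.22) or the C57BL/6 day 30 array (0.23). Smooth muscle and myofibroblast genes passed without the untreated C57BL/6 array on days 3, 30 and 60 (0.31, 0.18 and 0.51) and without the C57BL/6 day 60 array on day 60 (0.28). Neutrophil and endothelial genes passed on no day with any array left out. Whether the cell cycle, T and NK cell, sarcomere and smooth muscle lists pass depends on single arrays, so none of them is reported as changed.

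The other genes among the 10 largest and 10 smallest differences between the strains' changes on each day did not move 2-fold in opposite directions. Here too all days share the same untreated arrays. The MRL/MpJ change minus the C57BL/6 change (log2, 1 array on each side, without a test) on day 3 was 3.15 for Mfap4, a microfibril protein gene, 3.06 for Ptn, which encodes the growth factor pleiotrophin, -2.82 for Fbp2 and -2.68 for Klf15. On day 30 it was 3.34 for Spns1, 3.19 for Josd2, 3.08 for Sec13, 2.92 for Tbl2, 2.81 for Tiam1, -4.48 for Alas2, the heme synthesis gene of red blood cell precursors, and -3.60 for Tlr9. On day 60 it was 3.24 for Abca2, 2.80 for Phgdh, 2.77 for P2ry6, 2.58 for Ms4a6d, 2.49 for Inhbb, -2.99 for Pdzk1ip1 and -2.87 for Ccdc43.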
